A study of Homo sapiens with 6 samples.

How the data were processed

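Total RNA of PC9/GR cells was harvested with Trizol and made into libraries with an Ion Proton RNA-Seq kit, per the labels' protocols. The deposited table holds raw counts of reads per gene symbol for 54261 symbols, of which 25004 have no read in any library. The build is GRCh38, per the submitters' processing notes. The aligner, the counting tool, the annotation release and the strand setting are not given in the sources used here, nor are the siRNA sequences, the dose or the time of harvest. The table's columns carry the sample titles, which give the group and the repeat number of each library.

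The groups were 3 libraries of control siRNA and 3 of MYLK-AS1 knockdown. Total counts were 8867818, 10246759 and 10978513 in control replicates 1 to 3 and 11055408, 9530332 and 7551303 in knockdown replicates 1 to 3. A count of 3, taken as the floor for a gene with 0 reads, corresponds to between 0.274 and 0.410 CPM. Correlations of log2 CPM were 0.984 to 0.990 within the control, 0.977 to 0.985 within the knockdown and 0.938 to 0.957 between the groups. No library pair of a group differed by as little as sampling noise, since the chi-square statistic per degree of freedom was 2.38 or more. The labels give no sequencing batch or date.

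Differential expression was tested with edgeR 4.0.16 in R 4.3.3, with filterByExpr, TMM factors, a robust quasi-likelihood fit and the two-sided quasi-likelihood F test. Benjamini-Hochberg adjustment covered the 15391 genes that passed the filter, and the threshold was an adjusted p of 0.05. CPM are counts scaled to the TMM-adjusted library size. The SE of a log2 fold change is its size divided by the square root of the F statistic, an approximation. The common biological coefficient of variation was 11.8%. Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the 33 lists with at least 5 tested members, and again with an estimated correlation and with fry. Of 1018 list symbols 1016 were matched to the table, 88 of them through an older or mitochondrial symbol.

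The comparisons, tests, gene lists and the rule for named genes were fixed before the data were examined, as were the alternatives except those described as chosen afterwards. The rule names MYLK-AS1 and MYLK, then the 12 genes up and the 12 genes down with the greatest absolute log2 fold change. These needed to be past the threshold, at a mean of at least 10 CPM and without overlap of the groups, and clone names were left out. From each list it names up to 4 members with the lowest p, and for glutamine also SLC1A5, GLUD1, GLUL, MYC and EGFR. Some genes under this rule are not reported here. Genes outside this rule are described as chosen after their values were seen.

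Alternatives were RLE or upper quartile factors, no factors, no filter, a filter of 5 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, leaving out each library, the repeat number as a block, and other thresholds. Gene positions came from GENCODE release 29 on GRCh38. Its longest annotated 3' UTR per gene was searched for every word of 7 bases, over 9811 genes with a mean of at least 5 CPM and a 3' UTR of at least 50 bases. Word differences were taken after regression of the log2 fold change on length and GC content, while medians by word used the log2 fold change itself.

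The test was checked on counts simulated for these 15391 genes, 200 of them changed. It recovered 23 of 67 genes changed by 0.5 (log2), 49 of 67 changed by 1 and 64 of 66 changed by 2, and 12 of 148 calls were false. A list of 18 members shifted by 0.5 had an adjusted p of 5.1e-48 among the 33 lists, and 1 other list was called. The simulated genes were drawn independently, and no gene outside that list was changed in that run. In the data many genes changed and list members can be correlated, so this p does not show how sensitive camera was here. The word scan, run on shuffled fold changes of 9811 genes with a planted word, returned that word first.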

Results

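RNA was sequenced from 6 samples of PC9/GR, a human lung cancer cell line. Of these, 3 received a control small interfering RNA (siRNA) and 3 an siRNA against MYLK-AS1, a long non-coding RNA transcribed from the strand opposite MYLK, the gene of myosin light chain kinase. The series title names glutamine metabolism and resistance to inhibitors of the epidermal growth factor receptor as its question, and the comparison of the groups asks which transcripts differ after MYLK-AS1 is lowered. Library totals ran from 7551303 reads in knockdown replicate 3 to 11055408 in knockdown replicate 1. The labels do not say that the repeats came from separate cultures, so p-values of single genes measure only the spread between these samples, which may be technical. Camera p-values set list members against other genes. Word z values, their permutations and all bootstrap intervals take genes as the units, as if independent, and do not measure spread between samples. Poisson intervals and floors cover counting error only.

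MYLK-AS1 fell in the knockdown. It had 20, 16 and 19 reads in control replicates 1 to 3 and 0, 5 and 4 reads in knockdown replicates 1 to 3. Its level was 1.84 ± 0.351 CPM (counts scaled by library size; SD, n = 3) in the control and 0.357 ± 0.309 CPM (SD, n = 3) in the knockdown. The log2 fold change was -2.43 (SE 0.60), with an adjusted p of 0.00326 by edgeR's quasi-likelihood test. Over the summed reads, 55 against 9, the knockdown kept 17.8% of the control rate (95% exact Poisson interval 7.74% to 36.3%). The 0 reads of knockdown replicate 1 allow a level of up to 0.274 CPM, taken as 3 counts. A two-sided exact permutation test of the CPM values gave p = 0.1, the smallest that 3 against 3 samples can give. MYLK-AS1 (ENSG00000239523.5) lies on chromosome 3 from 123585542 to 123644568 on the plus strand of GRCh38. MYLK (ENSG00000065534.18) lies on the minus strand from 123610049 to 123884331. MYLK fell as well, from 44.5 ± 6.30 to 27.6 ± 1.58 CPM (SD, n = 3 each), a log2 fold change of -0.69 (SE 0.13, adjusted p = 0.000464). Of 980 annotated exon bases of MYLK-AS1, 133 lie inside MYLK exons, and the strand setting of the counting is not given, so reads of the pair cannot be fully told apart. The 3' UTR of MYLK holds 7 of the 8 bases CAGCTTAA, a word searched for after the data were seen. Of the 16 tested genes of the list fixed around the locus, 6 rose, among them PARP9, DTX3L and PDIA5, and 2 fell (7 and 2 adjusted over the list alone). Of all tested genes 42.0% passed the threshold. PARP9 is also a member of the interferon list, where 24 of 38 tested genes rose. The list around the locus as a whole did not pass with camera (adjusted p = 0.159, and 0.437 with an estimated correlation).

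**Figure D1:**
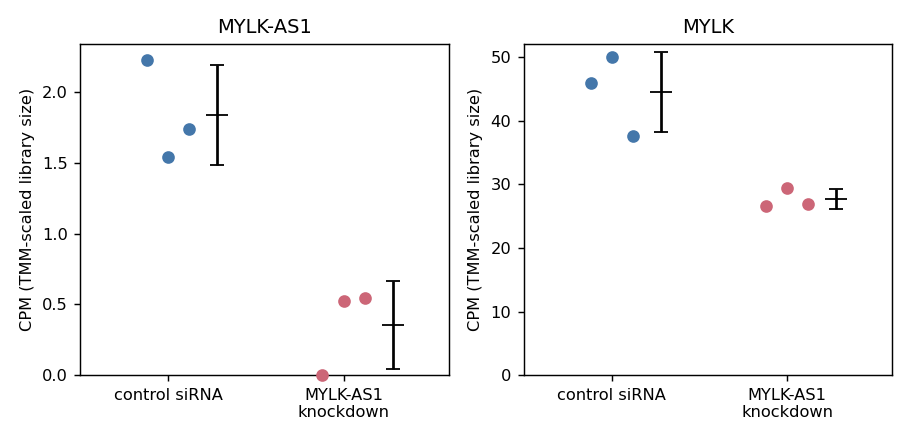
Levels of MYLK-AS1 (left) and MYLK (right) in CPM on the y axis, for control siRNA and MYLK-AS1 knockdown on the x axis. Each point is 1 library, and bars give the mean ± SD of 3. MYLK-AS1 lies between 0 and 0.546 CPM in the knockdown and between 1.54 and 2.22 CPM in the control.

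Of 15391 tested genes, 3274 rose and 3183 fell in the knockdown, and 8934 did not pass the adjusted p of 0.05. At least 2-fold changes numbered 646 upward and 1131 downward. The CPM values of the groups did not overlap for 8034 genes, 52.2% of those tested, where chance gives 10%. The first principal component of log2 CPM carried 65.7% of the variance and parted the groups. The second carried 12.97% and set knockdown replicate 3 apart from the other knockdown libraries.

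Among the 12 named genes with the greatest rise, 9 code for proteins. SLC16A6, a member of the monocarboxylate transporter family, rose from 11.1 ± 1.94 to 146 ± 11.1 CPM (SD, n = 3 each; log2 fold change 3.72, SE 0.13). HMOX1, the heme oxygenase that degrades heme, rose from 38.8 ± 1.75 to 249 ± 14.6 CPM (log2 fold change 2.68, SE 0.10). Both had an adjusted p of 3.43e-12. CPA4, a carboxypeptidase, rose by a log2 fold change of 3.99 (SE 0.18) and IGFBP1, an insulin-like growth factor binding protein, by 2.34 (SE 0.12). DHRS9 (2.91, SE 0.20), C11orf86 (2.80, SE 0.14), GLIPR1 (2.69, SE 0.15), FRRS1 (2.48, SE 0.26) and the interferon-inducible SAMD9 (2.43, SE 0.16) rose too. SLC16A6 has an annotated pseudogene copy, SLC16A6P1, with which reads may be shared. The other 3 were short RNAs without a poly(A) tail. RMRP, the RNA of RNase MRP, RN7SK, the 7SK RNA that restrains transcription elongation, and RN7SL1, the RNA of the signal recognition particle, had log2 fold changes of 5.07 (SE 1.38), 3.99 (SE 0.74) and 3.39 (SE 0.85). RMRP stood at 9.77, 17.6 and 87.0 CPM in knockdown replicates 1 to 3, so knockdown replicate 3 carried most of its mean. The calls of RMRP (adjusted p = 0.0474) and RN7SL1 (0.0379) were lost with limma-voom and without filtering, and those of all 3 were lost when any 1 control library was left out.

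Among the 12 with the greatest fall, TMEM30A led, the subunit that lipid flippases need to leave the endoplasmic reticulum. It fell from 134 ± 9.32 to 19.0 ± 3.43 CPM (SD, n = 3 each; log2 fold change -2.82, SE 0.13, adjusted p = 5.68e-11). The mucins MUC5AC and MUC16 fell, with log2 fold changes of -2.47 (SE 0.24) and -2.73 (SE 0.64), MUC5AC from 1021 ± 214 to 183 ± 46.1 CPM. MUC16 (adjusted p = 0.0279) lost its call without filtering and when control replicate 1, control replicate 2 or knockdown replicate 2 was left out. The chemokine CCL5 (-2.55, SE 0.20), the glucocorticoid-induced co-chaperone FKBP5 (-2.55, SE 0.17), the cysteine protease CTSV (-2.49, SE 0.21) and MXD3 (-2.40, SE 0.19), a member of the MYC and MAX network, fell. So did the mitochondrial outer membrane channel VDAC2 (-2.37, SE 0.14), the vesicle fusion ATPase NSF (-2.33, SE 0.20), the mitotic spindle protein PSRC1 (-2.24, SE 0.16), ND6 (-2.23, SE 0.36) and HMGN1P38 (-2.18, SE 0.19). VDAC2 and NSF have near-identical copies, HMGN1P38 is itself a pseudogene, and ND6 lies on the strand opposite the other mitochondrial mRNA genes, so these counts are uncertain. Of the 10 of these 12 genes with a searched 3' UTR, 7 hold the bases AGCTTA, against 2 of 9 among those that rose. The contrast was smaller over all scanned genes at least 4-fold lower, where 10 of 25 hold them (40%), against 27.7% of all scanned genes. TMEM30A holds the longer CAGCTTAA, and MXD3 and NSF hold 7 of those 8 bases. CCL5, FKBP5, CTSV and PSRC1 hold AGCTTA alone. Of all scanned genes with AGCTTA alone 20.9% were lower, against 19.3% of those without it. These shares take no account of 3' UTR length and GC content. After regression on both, genes with AGCTTA alone differed by -0.098 (log2; SE of their mean 0.017) from those without it.

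**Figure D2:**
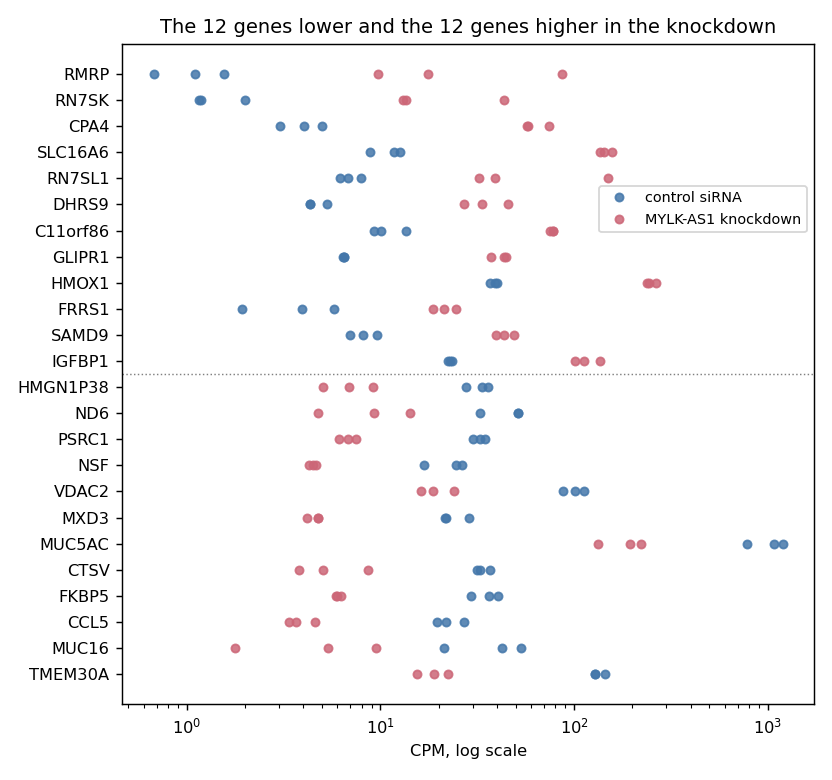
CPM on a log axis (x) of the 12 genes lower and the 12 genes higher in the knockdown (y), chosen by a fixed rule. Each point is 1 library, blue for control siRNA and red for MYLK-AS1 knockdown. MUC5AC falls from 1021 to 183 CPM on average, and RMRP spreads from 9.77 to 87.0 CPM within the knockdown.

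For the question of glutamine metabolism, transport and breakdown genes went both ways. The amino acid exchanger SLC7A5 rose from 670 ± 57.1 to 1659 ± 32.6 CPM (SD, n = 3 each; log2 fold change 1.31, SE 0.09, adjusted p = 9.6e-09), and the glutamine transporter SLC38A7 from 22.3 ± 0.881 to 61.7 ± 1.34 CPM (1.47, SE 0.12). GLUD1, the glutamate dehydrogenase that feeds the tricarboxylic acid cycle, fell from 131 ± 1.94 to 45.5 ± 3.27 CPM (-1.53, SE 0.10), and its near-identical copy GLUD2 fell too (-1.24, SE 0.12), with reads that may be shared between them. The main glutamine importer SLC1A5 had a log2 fold change of 0.20 (SE 0.09, adjusted p = 0.0783), and the glutamine synthetase gene GLUL one of -0.08 (SE 0.22, adjusted p = 0.791). Of the 18 tested members of the list of glutamine transport and glutaminolysis, 9 rose and 4 fell (10 and 4 adjusted over the list alone). The other fallen members were the aspartate aminotransferase GOT1 (-0.85), named after its value was seen, and OGDH (-0.58), a subunit of the oxoglutarate dehydrogenase complex. The list median was 0.29, and as a whole it did not pass the camera test (adjusted p = 0.0731, and 0.293 with an estimated correlation). The list passed with fry (adjusted p = 0.00243), which asks only whether members moved on balance in one direction, and with camera when control replicate 3 was left out (adjusted p = 0.0453). It also passed with camera among genes without AGCTTA in the 3' UTR (adjusted p = 0.00182), a restriction chosen after the data were seen. GLUD1, GLUD2 and GLUL hold AGCTTA in their 3' UTRs.

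Genes that use the amide nitrogen of glutamine changed less often than not. Of 11 tested, GFPT1 (0.78, SE 0.09), PPAT (0.89, SE 0.14) and the asparagine synthetase gene ASNS (0.67, SE 0.12) rose and none fell, the same count adjusted over the list alone. GMPS had 0.27 (adjusted p = 0.0615). The list did not pass (adjusted p = 0.184, and 0.538 with an estimated correlation). In glutathione synthesis and cystine uptake, 4 of 11 rose and 2 fell (4 and 2 adjusted over the list alone). GCLC (1.28, SE 0.11) and GCLM (1.06, SE 0.11), the subunits of the enzyme that starts glutathione synthesis, and the cystine transporter SLC7A11 (0.71, SE 0.11) rose, and the mitochondrial folate enzyme MTHFD2 fell (-1.20, SE 0.12). This list did not pass either (adjusted p = 0.159, and 0.437 with an estimated correlation).

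Of 33 lists with at least 5 tested members, out of 36 fixed, 14 passed the camera test, 7 upward and 7 downward. With an estimated correlation 1 of them passed, the list of G2 and mitosis. This list fell as a block. Of its 43 tested members, 40 fell and 0 rose (41 and 0 adjusted over the list alone), with a median log2 fold change of -1.25 (camera adjusted p = 6.26e-47, and 0.0258 with an estimated correlation). The spindle midzone protein PRC1 fell from 265 ± 5.77 to 65.3 ± 4.45 CPM (SD, n = 3 each; -2.02, SE 0.09). The mitotic kinesin KIF20A (-1.86, SE 0.10), the survivin gene BIRC5 (-1.81, SE 0.10) and the spindle protein SPAG5 (-1.65, SE 0.09) fell with it. Genes of DNA replication and S phase fell less, 27 of 43 with 1 that rose, the same counts adjusted over the list alone, and a median of -0.41. The thymidine kinase TK1 (-1.67, SE 0.11), the thymidylate synthase TYMS (-0.88, SE 0.10), the helicase subunit MCM4 (-0.94, SE 0.11) and CDC45 (-1.08, SE 0.13) were among them. The camera adjusted p was 9.88e-06, and 0.395 with an estimated correlation.

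The lists of NRF2 targets, glycolysis, MYC targets, ATF4, hypoxia and ribosomal proteins passed upward with camera, and none of them with an estimated correlation. Of 25 tested targets of the oxidative stress regulator NRF2, 14 rose and 4 fell, the same counts adjusted over the list alone, with HMOX1, SRXN1 (1.10, SE 0.09), GCLC and GCLM leading (camera adjusted p = 1.29e-05, and 0.293 with an estimated correlation). Of 22 glycolysis genes, 14 rose and 0 fell, also adjusted over the list alone. Lactate dehydrogenase LDHA rose from 1603 ± 42.5 to 3135 ± 196 CPM (0.97, SE 0.09), and PGAM1 (1.07, SE 0.12), ALDOA (0.71, SE 0.09) and the lactate transporter SLC16A1 (0.74, SE 0.10) rose too. That list had a camera adjusted p of 0.000221, and 0.332 with an estimated correlation. MYC itself rose from 153 ± 14.6 to 231 ± 6.70 CPM (0.59, SE 0.09). Of 51 tested MYC targets, 29 rose and 5 fell (30 and 5 adjusted over the list alone), with the ribosome assembly factors RRP12 (1.12, SE 0.12) and NIP7 (0.89, SE 0.12) and the spermidine synthase SRM (0.74, SE 0.10) up and MCM4 down. Its camera adjusted p was 0.000214, and 0.293 with an estimated correlation. Among 36 genes of the amino acid and stress response through ATF4, 18 rose and 8 fell (19 and 8 adjusted over the list alone). STC2 (1.57, SE 0.10), SLC7A5 and TRIB3 (1.06, SE 0.10) rose and the transcription factor CEBPB fell (-1.36, SE 0.12), with adjusted p = 0.0176, and 0.293 with an estimated correlation. This list did not pass when control replicate 2 was left out (adjusted p = 0.0552). Of 21 hypoxia response genes, 7 rose and 3 fell, the same counts adjusted over the list alone, with the oxygen sensor EGLN1 (1.19, SE 0.09) and P4HA1 (1.15, SE 0.09) up (adjusted p = 0.00861, and 0.437 with an estimated correlation). The hypoxia list was lost without control replicate 2 (adjusted p = 0.0552) and without knockdown replicate 1 (0.0521). Of 77 cytosolic ribosomal protein genes, 25 rose and 4 fell, the same counts adjusted over the list alone, RPS23 (0.67, SE 0.10) and RPL6 (0.62, SE 0.10) among those up. Its adjusted p of 0.0256, which became 0.611 with an estimated correlation, was lost without control replicate 1 (0.0919), control replicate 2 (0.0552) or knockdown replicate 1 (0.0644), with a stricter filter (0.0801) and among genes with no AGCTTA in the 3' UTR (0.202).

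The list of interferon-inducible genes passed upward with camera, with a wide spread between libraries. Of 38 tested, 24 rose and 5 fell (27 and 5 adjusted over the list alone), with SAMD9, the RNA sensor DDX58 (1.42, SE 0.12), IFIT5 (1.32, SE 0.12) and PARP9 (1.08, SE 0.11) leading. The camera adjusted p was 1.33e-07, and 0.437 with an estimated correlation. The members' correlation was estimated at 0.698. The median member lay 0.28 (log2) above the control mean in control replicate 3 and 0.27 above it in knockdown replicate 1. Without control replicate 1 the number that rose was 15, and without knockdown replicate 2 it was 14.

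The lists of lipid synthesis, NF-kB targets, epithelial markers, YAP targets and oxidative phosphorylation passed downward with camera, and none of them with an estimated correlation. Of 33 genes of cholesterol and fatty acid synthesis, 21 fell and 4 rose (22 and 4 adjusted over the list alone), with the desaturases FADS2 (-1.27, SE 0.09) and SCD (-0.80, SE 0.10), EBP (-0.91, SE 0.11) and the regulator SREBF1 (-1.20, SE 0.15) down. The camera adjusted p was 6e-05, and 0.115 with an estimated correlation. Of 23 NF-kB targets and cytokines, 15 fell and 2 rose, the same counts adjusted over the list alone. The adhesion molecule ICAM1 (-1.77, SE 0.15), TNFAIP2 (-0.88, SE 0.09) and CXCL3 (-1.43, SE 0.15) fell, and the cyclooxygenase gene PTGS2 rose (1.38, SE 0.10), with adjusted p = 0.000181, and 0.338 with an estimated correlation. Of 18 epithelial markers, 11 fell and 1 rose (12 and 2 adjusted over the list alone), the claudins CLDN1 (-1.37, SE 0.11) and CLDN7 (-2.24, SE 0.37) and the keratins KRT18 (-0.78, SE 0.09) and KRT8 (-0.67, SE 0.10) leading. Their camera adjusted p was 0.000797, and 0.293 with an estimated correlation. Without knockdown replicate 2 the number that fell was 7. Mesenchymal markers did not pass as a list (adjusted p = 0.0510, and 0.293 with an estimated correlation), though 8 of 19 rose, among them ITGA5 (1.43, SE 0.09) and LOXL2 (1.17, SE 0.10), and 3 fell, among them ACTA2 (-1.37, SE 0.14). Counts adjusted over the list alone were the same. Of 21 YAP and TEAD targets, 11 fell and 4 rose (12 and 4 adjusted over the list alone), with AMOTL2 (-1.38, SE 0.10), AJUBA (-1.34, SE 0.12) and ANKRD1 (-3.02, SE 0.35) down (adjusted p = 0.0014, and 0.293 with an estimated correlation). Of 69 nuclear genes of oxidative phosphorylation, 23 fell and 5 rose, the same counts adjusted over the list alone, with SDHA (-0.83, SE 0.09) and UQCRC2 (-0.72, SE 0.09) down (adjusted p = 0.00649, and 0.586 with an estimated correlation).

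**Figure D3:**
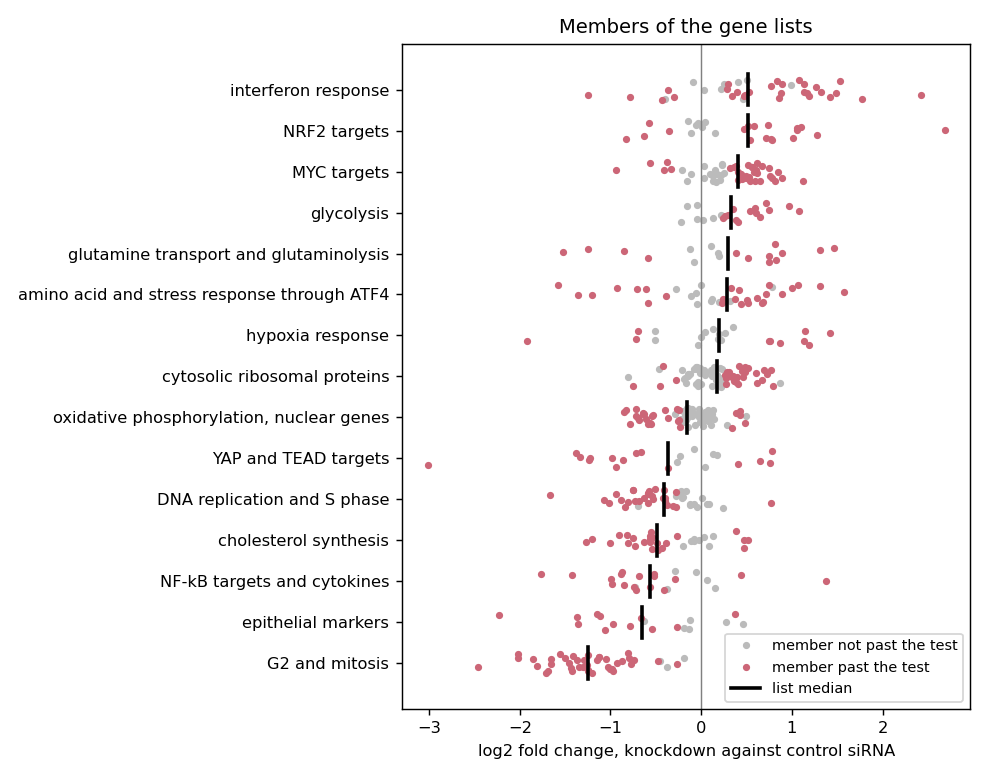
Log2 fold change (x) of the tested members of the 14 lists past the camera test and of the glutamine transport and glutaminolysis list (y). Points are genes, red if past the adjusted p of 0.05, and black bars are list medians. The G2 and mitosis list has a median of -1.25 and 0 members past the test on the right.

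Receptor and MAPK genes, which bear on response to inhibitors of the epidermal growth factor receptor, went both ways. EGFR was listed at 2.46 ± 0.807 CPM in the control and 3.36 ± 0.539 CPM in the knockdown (SD, n = 3 each; log2 fold change 0.47, SE 0.32, adjusted p = 0.26). The receptor ERBB3 fell from 40.5 ± 4.88 to 11.9 ± 1.63 CPM (-1.76, SE 0.15) and the receptor inhibitor ERRFI1 fell (-1.18, SE 0.12). The ligand EREG (1.81, SE 0.13) and the receptor MET (0.87, SE 0.10) rose. Over the list, 6 of 22 rose and 3 fell, also adjusted over the list alone (adjusted p = 0.629, and 0.695 with an estimated correlation). Its median was -0.06 and its mean 0.04. Of 22 MAPK output genes, 9 rose and 6 fell (9 and 7 adjusted over the list alone), with the cyclin CCND1 (2.27, SE 0.09), FOSL1 (1.17, SE 0.12) and PHLDA2 (1.35, SE 0.18) up and IER3 down (-1.04, SE 0.14). That list did not pass (adjusted p = 0.12, and 0.332 with an estimated correlation).

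Of markers of other cell types, 2 of 14 for blood, 1 of 10 for endothelium, 2 of 15 for squamous, 4 of 12 for fibroblast and 6 of 15 for neuroendocrine cells had at least 1 CPM in the control. UCHL1, named after its value was seen, was the highest at 637 CPM, followed by CD68 (193 CPM), ENO2 (147 CPM) and FBLN1 (122 CPM). CD68 and CD14, at 35.3 CPM in the control, were the 2 blood cell markers tested. The endothelial list had 1 tested gene, ESAM, which rose from 7.11 to 19.0 CPM, and the squamous list 2, KRT16 and DSC3, which rose to 2.27 and 6.38 CPM. Of 5 tested fibroblast markers, LUM rose, from 0.482 to 3.45 CPM, and FBLN1 and TWIST2 fell (1 and 3 adjusted over the list alone; list adjusted p = 0.373, and 0.635 with an estimated correlation). Its median was -0.38 and its mean 0.16. Of 9 lung epithelial lineage genes, KRT7 (-0.54, SE 0.10) and AGER (-0.92, SE 0.34) fell and none rose (1 and 0 adjusted over the list alone; list adjusted p = 0.382). Of 6 neuroendocrine markers, ENO2 (0.53, SE 0.10), SYP (0.78, SE 0.20) and SCG2 (0.75, SE 0.23) rose and none fell, also adjusted over the list alone (list adjusted p = 0.177).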

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

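Of the alternatives reported here, only the restriction to genes without AGCTTA and the recount of list members were chosen after seeing the data. The counts of 3274 genes higher and 3183 lower stayed within 1.5 times under RLE, upper quartile or no factors, no or a stricter filter, DESeq2, limma-voom and an adjusted p of 0.01. With a 2-fold minimum they were 646 and 1131, by construction smaller. Among genes whose searched 3' UTR holds no AGCTTA, 8632 of those tested, 2267 were higher and 1655 lower, again with fewer genes tested. Leaving out 1 library gave 2646 to 3176 higher and 2527 to 2971 lower. The MYLK-AS1 log2 fold change kept its side of the threshold throughout, at -2.95 to -1.74 when 1 library was left out. Under the stricter filter MYLK-AS1 was not tested. The number of lists past the threshold was 1 with an estimated correlation and 26 with fry, and 11 to 18 without 1 library (18 without control replicate 3). The glutamine transport and glutaminolysis list had an adjusted p of 0.00243 with fry and 0.00182 among genes without AGCTTA, where GLUD1, GLUD2 and GLUL drop out. It had 0.0453 to 0.0894 without 1 library, the lowest without control replicate 3, and the cause was not tested. Over its other alternatives it reached 0.293. Of 155 other named genes over the alternatives, 2102 of 2160 calls stayed on their side, 44 were lost and 13 gained. GLUL, not called, had log2 fold changes of -0.25 (without control replicate 2) to 0.15 (without control replicate 3), so its sign was reversed.

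The same repeat numbers occur in both groups, but deviations of same-numbered libraries correlated at -0.05, 0.07 and 0.05. These values show little shared deviation but cannot show whether equal numbers mark a shared culture or day. The labels do not say. With the replicate block 3321 genes were higher and 3200 lower, and 14 lists passed.

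Depth limits low genes such as MYLK-AS1, with 55 reads in the control. The simulation recovered 34.3% of changes of 0.5 (log2), a share not split by level. Far fewer genes changed in it than passed the threshold in the data, so the same adjusted p asked for a lower unadjusted p there. This share therefore does not show how sensitive the test of single genes was here, for low genes or others.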

Other observations

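The tests of where the word lies in MYLK-AS1, of its reordered bases, of a released microRNA, of library scaling, of cell cycle shares and of the short RNAs, and the genes looked up by level, were chosen only after the result was seen.

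The mitochondrial genome did not move as one. ND1 rose from 1517 to 2930 CPM (log2 fold change 0.95, SE 0.09) while ND4 fell from 7717 to 4685 CPM (-0.72, SE 0.10), COX1 fell (-0.41, SE 0.10) and ND6 fell (-2.23, SE 0.36). Of 13 genes 3 were higher and 5 lower (3 and 6 adjusted over the list alone), and the list did not pass (adjusted p = 0.275, and 0.611 with an estimated correlation). Genes of the BCL2 family changed in both directions, 4 of 14 up and 4 down, also adjusted over the list alone. The cell death activators BCL2L11 (1.03, SE 0.13), BMF (0.95, SE 0.12) and PMAIP1 (0.81, SE 0.14) rose, and the survival gene BCL2L1 fell (-0.66, SE 0.10). That list had an adjusted p of 0.638 (0.773 with an estimated correlation). Targets of p53 fell in 12 of 30 cases and rose in 7 (14 and 8 adjusted over the list alone), with FDXR (-1.50, SE 0.10), DDB2 (-1.31, SE 0.09) and RRM2B (-1.19, SE 0.14) down and the death receptor TNFRSF10B up (0.80, SE 0.09). Their adjusted p was 0.0759, and 0.293 with an estimated correlation. Of the 10 p53 targets with AGCTTA in the 3' UTR 7 were lower and 1 higher, and of the 20 without it 5 were lower and 6 higher. This split was made in every list, and its direction varied. Medians with and without AGCTTA were -0.27 and 0.37 for the ATF4 list but 0.05 and -0.51 for YAP and TEAD targets. Of 11 interferon genes with it 0 were lower and 7 higher.

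Autophagy and lysosome genes rose in 10 of 30 cases and fell in 2 (11 and 2 adjusted over the list alone), led by the autophagy receptor SQSTM1, from 1433 to 3716 CPM (1.37, SE 0.10), with the lysosomal membrane protein LAMP2 down (-0.72, SE 0.10). Its adjusted p was 0.0731, and 0.395 with an estimated correlation. In the unfolded protein response 8 of 20 rose, such as EDEM1 (1.11, SE 0.10) and DNAJB9 (1.31, SE 0.16), and 3 fell, such as SYVN1 (-1.44, SE 0.17), the same counts adjusted over the list alone. Its adjusted p was 0.111, and 0.332 with an estimated correlation. Of 28 TCA cycle genes 8 fell and 5 rose, also adjusted over the list alone, with SDHA down (-0.83, SE 0.09) and ME1 up (0.74, SE 0.10). That list had an adjusted p of 0.346, and 0.635 with an estimated correlation. Of 22 immediate early and heat shock genes 9 rose, HSPA8 (0.90, SE 0.11) and FOSB (2.44, SE 0.37) among them, and 2 fell, the same counts adjusted over the list alone (adjusted p = 0.0922, and 0.411 with an estimated correlation). Contractility genes rose in 4 of 17 cases and fell in 4, ACTA2 and MYLK among them, also adjusted over the list alone (adjusted p = 0.638, and 0.68 with an estimated correlation). Replication-dependent histones had 7 tested members, with HIST1H4H up and HIST1H3H down (1 and 0 adjusted over the list alone; adjusted p = 0.576, and 0.67 with an estimated correlation).

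Genes with a particular word in the 3' UTR had lower log2 fold changes than other genes after regression on length and GC content: of all 16384 words of 7 bases, AGCTTAA (1055 genes, difference -0.28, SE 0.02, z -15.3) and CAGCTTA (961 genes, -0.25, SE 0.02, z -13.3) had the lowest values, past the lowest z of 1000 permutations, -5.43, while the highest word on the other side had z 4.19 against a permutation maximum of 5.49. Release of a microRNA by MYLK-AS1 is argued against, since its reads were 0.00163% of those of genes with a word. Length and GC content of the 3' UTR are argued against as the source of the lower values. The log2 fold change rose with log length (r 0.115) and fell with GC content (r -0.156). Matching genes on both lowered the expected count of lower genes from 311 to 193, against 475 seen. The test of reordered words did not decide this. On chromosomes not used to find it AGCTTAA had -0.28 and -0.27 (SE 0.03 each). The lowest reorderings without AGCTT or GCTTA had -0.09 (SE 0.07) and -0.12 (SE 0.05), not parted from AGCTTAA by 2 SE of each. A candidate explanation is a seed match of the siRNA guide strand, since genes with the joined CAGCTTAA lay 0.21 lower than genes with a 7-base word (difference of medians -0.21, 95% bootstrap interval -0.29 to -0.13), and those lay below genes with the 6 bases alone. These medians were not adjusted for length or GC content, and they came from the same genes that picked the words. CAGCTTAA also occurs at 1 place in MYLK-AS1, on chromosome 3 from 123630774 to 123630781 of GRCh38, in exon 3 of a 760-base transcript, where 1.47% of 8-base words would occur. Genes with the word were a part of the response: of 1607 genes with a 7- or 8-base word 475 were lower and 348 higher. The lower count compares with 193 expected from genes matched by length and GC content or 311 without matching. That is an excess of 13.6% or 7.91% of the 2078 lower genes scanned. Counting AGCTTA alone as well, 707 of 2716 genes were lower, against 335 expected with the same matching, an excess of 17.9%. Of 16 named genes with a 7-base word 9 fell, such as MTHFD2 and ERBB3, and 4 rose, such as PARP9 and SLC7A11. Named genes were chosen by p or fold change, so their counts do not measure the effect of the word. The siRNA sequence is not given in the sources used here, and an siRNA of another seed or a rescue was not analysed here, so which of the other changes follow from loss of MYLK-AS1 stays open.

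Genes of G2 and mitosis were lower in the knockdown. Their own seed matches are argued against as the cause, since the 30 members without AGCTTA had a median of -1.28 (95% bootstrap interval -1.43 to -1.14). Library scaling, which shifts every gene alike, is argued against too, since the list median lay 1.25 below that of the 15348 other tested genes (difference -1.25, 95% bootstrap interval -1.41 to -1.05). That 40 of 43 members were lower may reflect a smaller share of cells in these phases or lower expression per cell, which cannot be told apart because no cells were counted by phase.

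Short RNAs without a poly(A) tail were higher in the knockdown, 8 of 9 in each of its libraries above every control library, with SNORD118 the exception. Of the 9, 4 passed the threshold. RMRP, RN7SK and RN7SL1 had already been named for passing it without overlap, and RN7SL3 was the other (adjusted p = 0.0156 by edgeR). RN7SL1, RN7SL2 and RN7SL3 are all 7SL RNAs, and SNORD3A and SNORD3D both U3 RNAs. Reads may be shared among such copies, so the 9 short RNAs are not independent. Carry-over of short RNA that differs between libraries is a candidate explanation, since 88.9% of them were highest in knockdown replicate 3 and their summed CPM differed 6.22-fold within the knockdown, against 1.11-fold within the control. More RNA polymerase III output stays open, since the 3 tested RNAs of polymerase II had a median of 5.08 but went both ways and were too few. Whether handling of the RNA or the knockdown raised them in the other knockdown libraries cannot be told apart.

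Some levels invite a second look, chosen after their values were seen. EGFR was listed at 1.56 to 3.98 CPM over the 6 libraries, CDKN2A and CDKN2B had 0 reads in each, MTAP had 13 to 38 reads and EPCAM 4 to 16. ALDH1A1 stood at 5722 CPM in the control, AKR1C2 at 3919, AKR1B10 at 2878 and ALDH3A1 at 2776. Together with AKR1C1 and AKR1C3 these aldehyde and ketone metabolising genes took 1.47% to 1.93% of the scaled reads. Genes that every cell uses were also listed near 0, with 5 reads in all for RPS29, 6 for EIF3C and 0 for HK1, a hexokinase, so a low listing does not show absence. No reference profile of this line was used here, and its identity was not tested.

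With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. The real split gave 3274 genes higher and 3183 lower against 0 in each of the others, and 14 lists against at most 11 in another split. In each count, 1 split of the 10 gave as many, the real one. Every other split mixes the groups and so adds their difference to the spread within groups. The 0 genes called there follow from this and are no measure of chance.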
